A study of Homo sapiens with 4 samples.

How the data were processed

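RNA sequencing was carried out on 4 libraries of A549 cells, a human lung adenocarcinoma line. Per the labels, lentiviral infection was used to make a stable control line and a stable line overexpressing CBX7, and each line gave 2 libraries from total RNA. The deposited table gives 1 estimated count per gene and library for 28278 genes, keyed by gene symbol. Per the submitters' processing notes, HISAT2 2.2.1, StringTie 2.2.1, DESeq2 and the human genome build hg38 were used; the notes assign no role to any of them. Because the deposited values are treated here as estimated counts, a 0 can be a failed estimate as well as an absence of reads. The gene annotation, the strandedness of the libraries and how reads shared between gene copies or overlapping genes were counted are not given in the sources used here.

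All deposited values were already whole numbers, so rounding changed none of them, and they entered the count models as they were. Every row carried a gene name, and all 4 count columns were matched to samples by their titles. Library totals were 88091494 and 69877585 counts for control libraries 1 and 2, and 90765502 and 88861255 for CBX7 libraries 1 and 2. A floor of 3 counts per library corresponded to 0.0348, 0.0440, 0.0320 and 0.0333 CPM in the same order. CPM, the depth-normalised read count used here, divides the count by the library total and by its TMM factor. Levels are given as mean ± SD over n = 2 libraries per group. Folds against a group with 0 counts in both libraries were computed against the floor of 3 counts per library and are lower bounds. For groups with 1 to 3 counts in total, the ratio is given with a 95% counting interval. Intervals and floors cover counting error only.

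The comparison was CBX7 overexpression against control, with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr, scaled with TMM, and tested with a quasi-likelihood model (robust estimation, group as the only term) on all 4 libraries. Every adjusted p for a gene is from this edgeR test with Benjamini-Hochberg adjustment, unless another tool is named. A gene was called at an adjusted p under 0.05, and larger changes were counted at a log2 fold change of 1 or more in size. Standard errors (SE) of log2 fold changes were derived from the fitted change and its F statistic. In total, 23398 genes had a count above 0 in at least 1 library and 17271 were tested. Chromosomes and positions of genes came from a RefSeq gene table of assembly GRCh38, matched by current symbol, which gave a chromosome for 95.9% of tested genes.

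Gene lists were tested with camera (limma 3.58.1) on voom log2 CPM with an inter-gene correlation of 0.01, adjusted over the 34 lists with 3 or more tested members. Member counts came from the edgeR fit, over all tested genes and adjusted over the list alone. Camera with an estimated correlation and fry were run beside it. That form of camera takes its p from the few degrees of freedom that 4 libraries leave, so it has little power over 34 lists. Failing it is not by itself a sign that list members are correlated. List medians were the same when members at 0 in 1 group were set to their bound. In all, 36 lists were written from general knowledge: the SOCS family, STAT3 targets, cytokines and chemokines, canonical PRC1, variant PRC1 and PRC2 subunits, the INK4-ARF locus, HOX genes, developmental Polycomb targets, epithelial and mesenchymal markers, invasion proteases, integrins and matrix, TGF-beta targets, Wnt targets, p53 targets, G1/S and G2/M genes, interferon-stimulated genes, antigen presentation, NRF2 targets, ATF4 and the unfolded protein response, cholesterol synthesis, glycolysis and hypoxia, lung lineage genes, immediate early genes, YAP targets, metallothioneins, heat shock genes, ribosomal proteins, mitochondrially encoded genes, replication-dependent histones, and markers of fibroblasts, leukocytes, endothelium and of kidney and cervix lines. Some genes stand in more than 1 list, so lists are not independent of each other.

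The groups, the tests, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except for 4 alternatives that are identified where they are used. By that rule the text names CBX7 and SOCS3. It also names the 12 genes with the largest rise and the 12 with the largest fall among called genes with a mean normalised count of 50 or more in the higher group, no overlap between the groups and a symbol that is not a clone, antisense, pseudogene or long non-coding series name. In each list it names up to 4 members with the smallest p, and up to 2 with the highest counts where no member was called, but some genes that the rule selects are left out of the text. Other genes that are named, such as IFNB1, CDH1, ZEB1, the members behind small counts and those in the weighing of explanations, were chosen after their values were seen.

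Each count test was checked on simulated counts drawn from the control means, the library sizes and the trended dispersion of these libraries. In them 200 genes with a control mean count of 50 or more were changed by 2-fold or 4-fold, equally up and down. For this comparison edgeR recovered 66% of 2-fold and 90% of 4-fold changes over 16629 simulated genes, and 6 of its 162 calls (3.70%) were false. DESeq2 recovered 66% and 94%, with 13 of 174 calls (7.47%) false, and limma-voom 64% and 89%, with 5 of 158 (3.16%) false. The real calls were far more numerous (4208) and included far larger falls, so these shares need not hold for them. Alternatives changed 1 choice at a time, except that the DESeq2 test also used its own scaling and gene filter (18463 genes): DESeq2 size factors, library totals alone, no low-count filter, a mean count of 50 or more, the DESeq2 1.42.0 Wald test, limma-voom, estimation that is not robust, an adjusted p under 0.01, the replicate number as a block, and leaving out each library in turn. When a library is left out, the lone library of its group is assumed to vary like the other group. Lists under library totals, member counts under other scalings, a STAT3 list without members shared with the interferon, cytokine and antigen lists, and the estimated correlation for that list were added after seeing the data. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15. Raw reads, transcript-level estimates and chromatin data were not analysed here.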

Results

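Gene expression was measured by RNA sequencing in A549 cells carrying either a control construct (2 libraries) or a CBX7 expression construct (2 libraries). Total estimated counts ranged from 69877585 in control library 2 to 90765502 in CBX7 library 1. Between 19678 and 20379 genes had a count above 0 in each library. Across genes, which are not independent replicates, Pearson's r of log2 CPM was 0.973 between the control libraries, 0.978 between the CBX7 libraries and 0.945 to 0.948 between libraries of different groups. Replicates differed by more than sampling noise (chi-square per degree of freedom of 58.5 for the controls and 45.5 for the CBX7 libraries), so none was taken to be a repeat entry of another; this does not show separate cultures. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. CPM values are mean ± SD with n = 2 throughout, and fold changes are CBX7 overexpression over control.

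The design asks which genes respond when CBX7, a chromobox subunit of Polycomb repressive complex 1 (PRC1), is overexpressed, and the series title points to repression of SOCS3, a feedback inhibitor of cytokine signalling. CBX7 transcripts rose 2.17-fold, from 8.37 ± 0.521 to 18.1 ± 1.31 CPM (n = 2), and SOCS3 fell 4.37-fold, from 42.3 ± 2.12 to 9.67 ± 2.04 CPM (n = 2). Far larger falls were found among genes of the interferon response: the antiviral sensor OAS2 went from 862 ± 122 to 0.618 ± 0.138 CPM, and all 39 tested interferon-stimulated genes fell. With them fell 25 of 31 cytokine, 14 of 19 antigen presentation and 23 of 32 immediate early genes, while 20 of 31 NRF2 targets, 15 of 25 cholesterol synthesis genes and the mucins MUC5AC and MUC5B rose. Without untransduced cells in the series, it cannot be told whether CBX7 removed the interferon programme or the control line alone gained it. Of the 20 gene lists that passed camera, 0 passed with an estimated correlation, a form with little power at 4 libraries.

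CBX7 (chromosome 22, 39130772 to 39152680, GRCh38) had 689 and 596 counts in the controls and 1783 and 1550 with overexpression, a log2 fold change of 1.11 (SE 0.156, adjusted p = 0.000141). A gene-level count does not separate transcripts of the construct from those of the endogenous gene. SOCS3 (chromosome 17, 78356778 to 78360925, GRCh38) had 3771 and 2783 counts in the controls and 1040 and 742 with overexpression, a log2 fold change of -2.13 (SE 0.153, adjusted p = 1.87e-07). In both genes the difference between groups exceeded the spread between replicates.

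**Figure D1:**
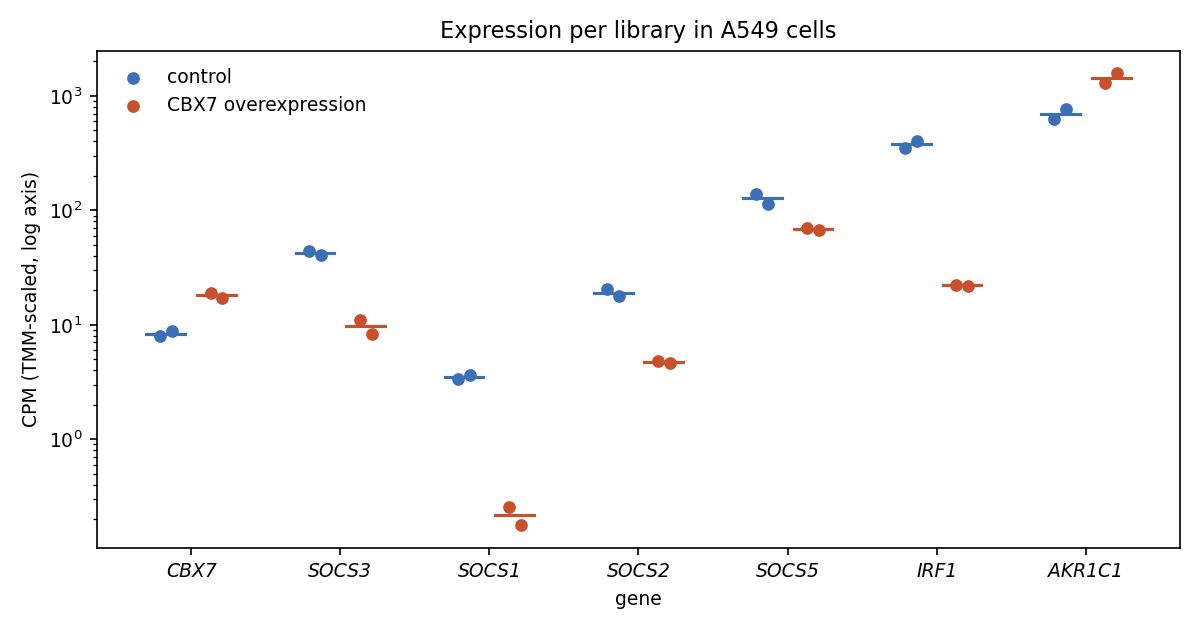
CPM per library on a log axis for 7 genes, with a point for each of the 2 libraries per group and a bar at the group mean. CBX7 and AKR1C1 sit higher with CBX7 overexpression (CBX7 at 18.1 against 8.37 CPM), and SOCS3, SOCS1, SOCS2, SOCS5 and IRF1 sit lower.

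Among 17271 tested genes, 4208 (24.4%) were called, of which 1809 were higher and 2399 lower. Changes of 2-fold or more numbered 364 higher and 926 lower. The largest rises were in genes of low abundance. KRT79, a keratin, had 0 counts in both controls and 101 in each CBX7 library, at least 27.9-fold higher (adjusted p = 0.000134), and CIB4 was at least 15.6-fold higher (adjusted p = 0.0022). Both belong to the 13 genes at 0 in both controls, for which zeros left by count estimation are not excluded. These bounds hold only if the zeros are true absences of reads. SPDEF, a transcription factor of secretory epithelium, rose 7.78-fold from 1.82 ± 0.894 CPM (log2 fold change 2.96, adjusted p = 1.32e-05). VIL1, the actin-bundling protein villin of brush borders, rose from 1.19 ± 0.204 to 8.86 ± 2.09 CPM (log2 fold change 2.90, adjusted p = 3.35e-06), and FMO5, a flavin monooxygenase, from 0.582 ± 0.380 to 4.26 ± 0.911 CPM (log2 fold change 2.89, adjusted p = 0.000301). UGT2B15, a glucuronosyltransferase with close paralogs, and PDE1A, RBP4, KCNJ16, SLA2, SLC1A7 and ADH6 rose by log2 fold changes of 2.60 to 4.68 from levels of 0.0366 to 0.143 CPM. The sizes of these rises are uncertain. UGT2B15, PDE1A and RBP4 had 0 counts in 1 control library, and with 1 library left out their log2 fold changes ran from 3.62 to 9.37, from 2.95 to 9.51 and from 2.84 to 8.82. Those of KCNJ16 ran from 2.79 to 4.21, of ADH6 from 1.95 to 3.31, of FMO5 from 2.33 to 3.77 and of SPDEF from 2.52 to 3.57.

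The largest falls were led by GBP4, an interferon-induced GTPase, which went from 46.8 ± 14.3 CPM to 0 counts in both CBX7 libraries, at least 1434-fold lower (adjusted p = 1.29e-06). The lambda interferons IFNL2 (35.6 ± 6.89 CPM in controls) and IFNL1 (26.4 ± 7.01 CPM) were also at 0 with overexpression, at least 1089-fold and 807-fold lower. IFNL3 had 2 counts left, a ratio of 2556 with a counting interval of 707 to 21110; its sequence is nearly identical to that of IFNL2, so the split between them is uncertain. The chemokine CXCL10 fell from 12.6 ± 5.01 CPM to 2 counts, a ratio of 1200 (332 to 9914), and CXCL11 from 15.4 ± 8.79 CPM to 0, at least 471-fold. DAPP1, ACTN2, NRIR, TNFRSF14 and CARD16 were at 0 in both CBX7 libraries as well, at least 50.6-fold to 98.3-fold lower. As with the rises from 0, all bounds for falls to 0 hold only if the zeros are true absences of reads. The sizes of falls to so few counts are uncertain: with 1 library left out, the log2 fold change ran from -14.1 to -10.2 for IFNL3, from -13.0 to -9.10 for CXCL10 and from -13.9 to -12.6 for CXCL11, whose controls had 1860 and 625 counts. OAS2 fell by 10.44 on the log2 scale (SE 0.188, adjusted p = 1.99e-13).

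The number of genes called higher rested on both CBX7 libraries: it was 1021 without CBX7 library 1 and 1121 without CBX7 library 2. Library totals in place of TMM, which move the median of all genes by 0.066, gave 2487 higher and 2033 lower genes, so that more genes were higher than lower. Single genes lost their call when a library was left out: RBP4 without control library 2 (adjusted p = 0.0685) or CBX7 library 1 (0.0801), KCNJ16 without control library 1 (0.0727), control library 2 (0.0763) or CBX7 library 2 (0.353), ADH6 without control library 2 (0.100) or CBX7 library 2 (0.342), and SLC1A7 without control library 1 (0.122), control library 2 (0.0737), CBX7 library 1 (0.196) or CBX7 library 2 (0.155). KCNJ16 and ADH6 also lost it with limma-voom (0.0618 and 0.0602). CXCL11 lost its call with no low-count filter (0.0884) and at a mean count of 50 or more (0.0867).

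**Figure D2:**
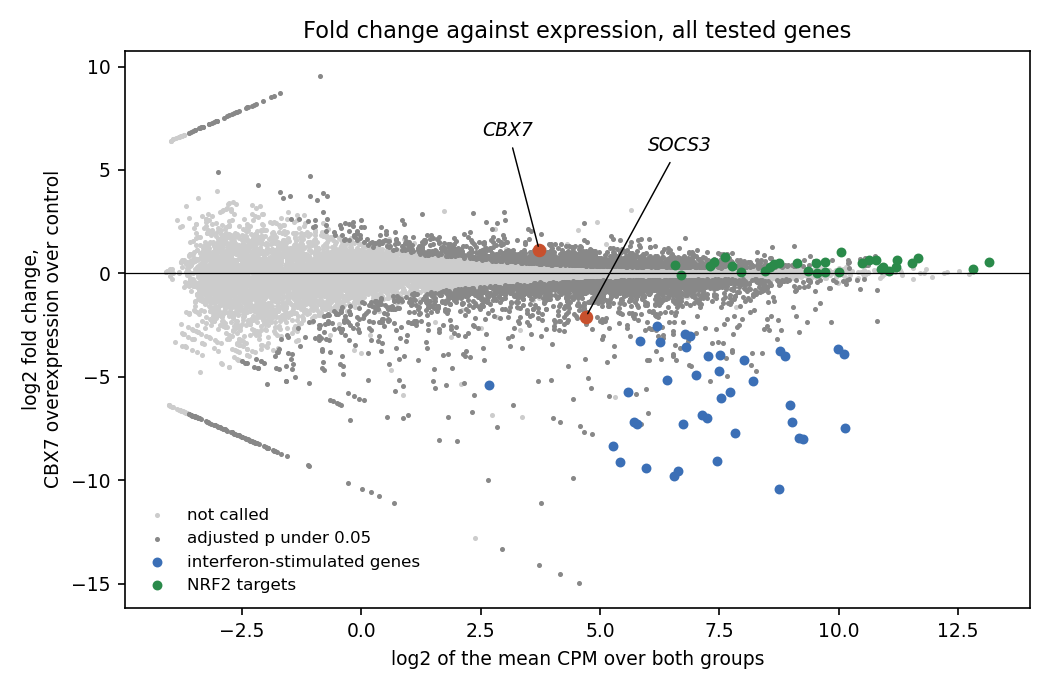
Log2 fold change of CBX7 overexpression over control against log2 mean CPM for the 17271 tested genes, with called genes in dark grey, interferon-stimulated genes in blue, NRF2 targets in green, and CBX7 and SOCS3 labelled. The 39 interferon-stimulated genes lie below 0, and the straight diagonal bands are genes at 0 counts in both libraries of a group, whose plotted change depends on the model's prior count.

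Interferon-stimulated genes, which encode antiviral effectors and interferon signalling factors, fell without exception. All 39 tested members were lower over all tested genes, as they were adjusted over the list alone, with a median log2 fold change of -5.75 (camera adjusted p = 5.15e-60; adjusted p = 0.211 with an estimated correlation). RSAD2 (viperin) fell from 349 ± 47.5 to 0.652 ± 0.0443 CPM, XAF1 from 186 ± 24.4 to 0.207 ± 0.00546 CPM and IFI44 from 124 ± 11.5 to 0.179 ± 0.0337 CPM, with adjusted p of 1.99e-13, 2.96e-13 and 3.85e-13. The RNA sensors DDX58 (RIG-I) and IFIH1 (MDA5) fell with log2 fold changes of -5.23 and -5.74. IFNB1, which encodes interferon beta, had 2035 and 1196 counts in the controls against 31 and 0 and was not called (adjusted p = 0.0831).

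Genes of antigen presentation fell with the interferon response. Of 19 tested members, 14 were lower, 2 higher and 3 not called, and 15 were lower and 2 higher adjusted over the list alone. The median log2 fold change was -2.16 (camera adjusted p = 7.39e-16; adjusted p = 0.211 with an estimated correlation). The peptide transporter TAP1 fell from 540 ± 6.12 to 37.7 ± 0.917 CPM, the class I transactivator NLRC5 from 174 ± 0.735 to 11.6 ± 0.148 CPM, HLA-B from 630 ± 82.3 to 44.3 ± 1.61 CPM and the immunoproteasome subunit PSMB9 17.8-fold to 8.19 ± 0.415 CPM. HLA-DMA and HLA-DMB, which load peptides onto class II molecules, were the members that rose, by log2 fold changes of 1.20 and 2.45. HLA genes share reads with their paralogs, so the level of any single one is uncertain.

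Cytokines, chemokines and NF-kB feedback genes were lower. Of 31 tested members, 25 were lower, none was higher and 6 were not called; adjusted over the list alone, 26 were lower and LCN2 was higher. The median log2 fold change was -2.62 (camera adjusted p = 8.25e-20; adjusted p = 0.211 with an estimated correlation). TNFAIP3, a brake on NF-kB signalling, fell from 123 ± 7.43 to 6.67 ± 0.145 CPM (log2 fold change -4.21, adjusted p = 9.27e-12). The neutrophil chemokines CXCL8 and CXCL2 fell with log2 fold changes of -2.88 and -2.72, and BIRC3, an inhibitor of apoptosis, with -2.50. IL6 was near the detection floor, with 45 and 8 counts in the controls and 3 and 0 with overexpression (adjusted p = 0.0621).

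SOCS3 was not the only suppressor of cytokine signalling to fall. In the SOCS family, 4 of 8 tested members were lower, none was higher and 4 were not called; adjusted over the list alone the same 4 were lower and SOCS7 was higher. SOCS1 fell from 3.51 ± 0.181 to 0.217 ± 0.0558 CPM (log2 fold change -4.00, adjusted p = 7.82e-06), SOCS2 from 19.1 ± 1.85 to 4.74 ± 0.106 CPM (log2 fold change -2.01, SE 0.168, adjusted p = 8.98e-07) and SOCS5 from 127 ± 18.7 to 68.2 ± 2.15 CPM (log2 fold change -0.89, adjusted p = 8.99e-05). The family median was -0.53 (camera adjusted p = 0.0114; adjusted p = 0.334 with an estimated correlation).

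The STAT3 list holds genes induced by IL-6 family cytokines, SOCS3 among them, and also receptors and kinases of the pathway such as LIFR and JAK2. Over all tested genes 17 of 29 were lower, 5 higher and 7 not called, against 17 lower and 6 higher adjusted over the list alone (median log2 fold change -0.54, camera adjusted p = 0.000117; adjusted p = 0.347 with an estimated correlation). IRF1 fell from 376 ± 41.2 to 22.2 ± 0.338 CPM, JUNB from 81.8 ± 6.11 to 13.1 ± 0.425 CPM and the survival factor MCL1 from 534 ± 57.9 to 203 ± 5.37 CPM. STAT3 itself fell by 0.68 on the log2 scale (adjusted p = 0.000104). The 5 that rose were the fibrinogen chains FGA, FGB and FGG, the hypoxia factor HIF1A and the mitotic gene BIRC5, with log2 fold changes of 0.34 to 1.89.

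Immediate early genes, the first transcriptional response to growth factors and stress, were lower. Of 32 tested members 23 were lower, 3 higher (JUND, ETV4 and KLF2) and 6 not called, with 24 lower and 3 higher adjusted over the list alone. The median log2 fold change was -1.07 (camera adjusted p = 4.19e-14; adjusted p = 0.250 with an estimated correlation). ATF3 fell from 229 ± 29.3 to 10.1 ± 0.0286 CPM, FOSL1 from 117 ± 3.86 to 17.8 ± 1.21 CPM and JUN from 113 ± 13.7 to 17.8 ± 0.339 CPM.

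Direct targets of p53, which is wild type in A549 cells, were lower. Of 32 tested members 21 were lower, none was higher and 11 were not called; 24 were lower and ZMAT3 was higher adjusted over the list alone (median log2 fold change -0.63, camera adjusted p = 2.14e-11; adjusted p = 0.273 with an estimated correlation). The growth arrest genes GADD45A and BTG2 fell with log2 fold changes of -2.68 and -2.25, and AEN and PLK2 with -1.52 and -1.42. In the list for ATF4 and the unfolded protein response, 16 of 33 members were lower, 3 higher (SDF2L1, SLC7A11 and SLC7A5) and 14 not called, with 17 lower and 3 higher adjusted over the list alone. Its median was -0.28 (camera adjusted p = 3.14e-05; adjusted p = 0.211 with an estimated correlation). Besides ATF3, it was led by DDIT3 (CHOP), which fell from 71.8 ± 5.89 to 6.30 ± 0.589 CPM, and by STC2 and CEBPB, with log2 fold changes of -2.06 and -1.25. The metal-binding protein MT2A fell from 402 ± 1.89 to 66.5 ± 1.64 CPM (adjusted p = 8.99e-11) and was the 1 of 3 tested metallothioneins to be called, also adjusted over the list alone. MT1F (0.649 ± 0.0974 to 0.283 ± 0.0233 CPM) and MT1X (23.1 ± 0.432 to 21.4 ± 0.0117 CPM) were not called, with adjusted p of 0.276 and 0.597. The metallothionein median was -1.19 (camera adjusted p = 0.0299; adjusted p = 0.389 with an estimated correlation), and the list passed no longer without control library 2 (adjusted p = 0.0701).

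NRF2 targets, oxidative stress genes driven by a factor that is constitutively active in A549 cells, rose. Over all tested genes 20 of 31 were higher, none was lower and 11 were not called, and 23 were higher adjusted over the list alone (median log2 fold change 0.40, camera adjusted p = 7.34e-11; adjusted p = 0.211 with an estimated correlation). The aldo-keto reductases AKR1C1 and AKR1C2 rose from 698 ± 102 to 1428 ± 201 CPM and from 2412 ± 64.6 to 4018 ± 367 CPM, though their near-identical sequences leave the split between them uncertain. EPHX1, an epoxide hydrolase, rose 1.71-fold and PGD, of the pentose phosphate pathway, rose 1.57-fold. Cholesterol synthesis genes also rose: 15 of 25 were higher, 2 lower (STARD4 among them) and 8 not called, with 18 higher and 3 lower adjusted over the list alone. Their median was 0.50 (camera adjusted p = 8.11e-07; adjusted p = 0.273 with an estimated correlation). LSS, DHCR7 and TM7SF2, enzymes of sterol synthesis, rose 2.03-fold, 1.78-fold and 2.29-fold.

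Polycomb subunits that were called changed by less than CBX7 itself. Among 14 canonical PRC1 subunits, CBX7, CBX2, CBX8 and CBX6 were higher, PHC2 was lower and 9 were not called, with the same counts of 4 and 1 adjusted over the list alone (median log2 fold change 0.012, camera adjusted p = 0.364). CBX2 rose from 40.7 ± 0.0913 to 63.9 ± 3.60 CPM, CBX8 from 14.7 ± 2.24 to 20.6 ± 1.39 CPM, and PHC2 fell from 72.5 ± 6.55 to 44.0 ± 2.30 CPM. BMI1 was counted unevenly between replicates, with 2924, 2798, 5065 and 1379 counts in control 1, control 2, CBX7 1 and CBX7 2 against 4631, 2087, 1137 and 4595 for the overlapping read-through gene COMMD3-BMI1, so its level is uncertain. Of 16 variant PRC1 subunits 6 were lower and 10 not called, with 6 lower adjusted over the list alone as well; PCGF5, RYBP, PCGF1 and BCOR fell, with log2 fold changes of -0.78 to -0.43 (list median -0.13, camera adjusted p = 0.0542). Of 14 PRC2 subunits 6 were lower and 8 not called, again 6 adjusted over the list alone; MTF2, EZH1, AEBP2 and EPOP fell, with log2 fold changes of -0.67 to -0.55 (list median -0.18, camera adjusted p = 0.0821). The catalytic subunit EZH2 was at 66.7 ± 2.42 and 63.8 ± 3.20 CPM (adjusted p = 0.734). Leaving out 1 library ended the calls of CBX8 (adjusted p of 0.118 without control library 2, 0.225 without CBX7 library 1 and 0.0606 without CBX7 library 2), PCGF1 and BCOR (0.0679 and 0.140 without CBX7 library 1), AEBP2 (0.0576 without control library 1) and EPOP (0.0961 without CBX7 library 2). It brought the variant PRC1 list past the threshold without control library 2 (adjusted p = 0.0399), as did the replicate block (0.0454), but it did not pass with an estimated correlation (0.408).

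Classic targets of Polycomb repression moved both ways. Of 29 tested HOX genes HOXB13, HOXC6 and HOXB5 were higher, HOXB9 was lower and 25 were not called, with 2 higher and 1 lower adjusted over the list alone (median log2 fold change 0.022, mean -0.0067, camera direction up, adjusted p = 0.656). HOXB9 fell from 22.6 ± 3.27 to 13.2 ± 0.486 CPM, HOXB13 rose from 6.74 ± 0.253 to 10.9 ± 0.142 CPM, HOXC6 from 0.889 ± 0.138 to 2.37 ± 0.863 CPM and HOXB5 from 9.47 ± 0.417 to 13.4 ± 0.231 CPM. Developmental Polycomb targets had 9 of 56 members higher, 9 lower and 38 not called, with 9 higher and 13 lower adjusted over the list alone (median -0.08, camera adjusted p = 0.257). The transcription factors TBX3, GATA6 and GATA3 were among those that fell, with log2 fold changes of -1.48, -1.37 and -1.33. At the INK4-ARF locus, known to be deleted in A549 cells, CDKN2A had 0 and 5 counts in the controls and 0 and 4 with overexpression. Its neighbour MTAP had 651 and 439 counts in the controls and 779 and 704 with overexpression (adjusted p = 0.509, not called over the list alone either). The 3 HOX rises lost their call when a library was left out: HOXB13 without CBX7 library 1 (adjusted p = 0.0661) or 2 (0.0769), HOXC6 without control library 1 (0.0516), control library 2 (0.0978) or CBX7 library 2 (0.273), and HOXB5 without control library 1 (0.0902), CBX7 library 1 (0.208) or CBX7 library 2 (0.156).

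Genes of epithelial state, matrix remodelling and invasion bear on the metastasis named in the series title. The receptor kinase AXL fell from 313 ± 0.376 to 132 ± 1.85 CPM and ZEB2, an inducer of epithelial-mesenchymal transition, from 8.42 ± 2.82 to 0.529 ± 0.0832 CPM, while fibronectin (FN1) rose from 1130 ± 52.7 to 1861 ± 7.36 CPM. Of 32 mesenchymal markers FN1 was higher, 9 were lower, VIM and ZEB1 among them (log2 fold changes of -0.40 and -0.59), and 22 were not called, with 2 higher and 9 lower adjusted over the list alone. Their median was -0.017, or 0.051 with library totals (camera adjusted p = 0.231). Of 35 epithelial markers 9 were higher, 4 lower and 22 not called, with 11 higher and 5 lower adjusted over the list alone (median 0.28, camera adjusted p = 0.0557). The tight junction gene CLDN1 and the desmosomal DSP fell with log2 fold changes of -1.17 and -0.82, and JUP and CLDN2 rose by log2 fold changes of 1.06 and 0.67. E-cadherin (CDH1) was at 42.4 ± 11.1 and 45.9 ± 1.93 CPM (adjusted p = 0.657).

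Of 34 tested matrix proteases and inhibitors, 12 were lower, 3 higher (MMP24, CTSV and TIMP4) and 19 not called, with 13 lower and 3 higher adjusted over the list alone (median log2 fold change -0.21, camera adjusted p = 0.0396; adjusted p = 0.273 with an estimated correlation). PLAUR, the urokinase receptor, fell 2.93-fold and cathepsin L (CTSL) 2.18-fold, while MMP24 rose 2.03-fold. This list passed no longer without control library 1 (adjusted p = 0.0907) or CBX7 library 2 (0.0537), nor at a mean count of 50 or more (0.115). TGF-beta targets had 15 of 26 members lower, 3 higher (BAMBI, CCN2 and TGFBR1) and 8 not called, with the same counts of 15 and 3 adjusted over the list alone. Their median was -0.53 (camera adjusted p = 0.000417; adjusted p = 0.273 with an estimated correlation), and JUNB, ANGPTL4 and BHLHE40 were among those with the lowest p, the last 2 with log2 fold changes of -1.58 and -0.93. YAP targets had 13 of 23 members lower, 2 higher (AMOTL1 and CCN2) and 8 not called, with 15 lower and 2 higher adjusted over the list alone (median -0.45, camera adjusted p = 1.75e-05; adjusted p = 0.273 with an estimated correlation). Besides GADD45A and AXL, the kinase NUAK2 and the ectonucleotidase NT5E (CD73) led them and fell 3.90-fold and 2.17-fold.

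Most cell cycle genes were not called. Of 43 mitotic (G2/M) genes 10 were higher, BUB1 was lower and 32 were not called, with 15 higher and 1 lower adjusted over the list alone and 22 higher with library totals (median log2 fold change 0.24, camera adjusted p = 3.12e-05; adjusted p = 0.211 with an estimated correlation). KIF11, ASPM and MKI67 rose 1.34-fold, 1.39-fold and 1.26-fold, and BUB1 fell 1.30-fold. Of 40 replication (G1/S) genes 6 were higher, none was lower and 34 were not called, with 5 higher adjusted over the list alone and 10 with library totals (median 0.08, camera adjusted p = 0.0114; adjusted p = 0.273 with an estimated correlation). E2F1, EXO1 and CCNE2 rose 1.52-fold, 1.43-fold and 1.92-fold. Without CBX7 library 1 the G1/S list did not pass (adjusted p = 0.0716), and neither did KIF11 (0.110), ASPM (0.0865), MKI67 (0.155), BUB1 (0.0884) and EXO1 (0.0511). Other left-out libraries ended the calls of KIF11 and ASPM (0.0556 and 0.0896 without control library 2), MKI67 (0.0748 without control library 1) and BUB1 (0.167 without CBX7 library 2).

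Replication-dependent histones, whose transcripts generally lack poly(A) tails and whose level can depend on how RNA was selected, were mostly not called. Of 37 tested 7 were lower, none was higher and 30 were not called, with 7 lower adjusted over the list alone too (median log2 fold change -0.84, camera adjusted p = 0.00474; adjusted p = 0.383 with an estimated correlation). H2BC21 fell from 29.2 ± 2.85 to 5.93 ± 1.43 CPM, H4C5 from 3.48 ± 0.773 to 0.364 ± 0.0135 CPM, H2AC6 from 19.4 ± 2.43 to 9.27 ± 1.75 CPM and H2BC5 from 19.2 ± 2.69 to 10.4 ± 0.820 CPM. The histone list passed no longer without CBX7 library 1 (adjusted p = 0.189) or with fry (0.0811). Of 78 ribosomal protein genes RPL9 was lower (21.8 ± 1.01 to 16.2 ± 2.24 CPM, adjusted p = 0.0468) and 77 were not called, while none was called adjusted over the list alone. As a set they lay slightly up (median 0.08, camera adjusted p = 0.0322; adjusted p = 0.781 with an estimated correlation), and with library totals 5 were higher and none was lower. RPS3 (1024 ± 126 to 1251 ± 71.2 CPM), RPL7 (466 ± 37.0 to 557 ± 60.1 CPM) and RPLP0 (1778 ± 172 to 2112 ± 234 CPM) were not called, but passed under several alternatives. RPS3 did so with DESeq2 (adjusted p = 0.0184), limma-voom (0.0382), library totals (0.0202), no low-count filter (0.0316), a mean count of 50 or more (0.0296), the replicate block (0.00649) and without control library 2 (0.0353). RPL7 did so with DESeq2 (0.0447), library totals (0.0347) and the replicate block (0.0250), and RPLP0 with library totals (0.0354), the replicate block (0.00919) and without CBX7 library 1 (0.0324). The RPL9 call was lost without control library 1 (0.0617) or 2 (0.129) and without CBX7 library 1 (0.414) or 2 (0.0585), with library totals (0.0809) and without robust estimation (0.0582), and the ribosomal list passed no longer without control library 1 (0.354) or CBX7 library 2 (0.950). None of the 13 mitochondrially encoded genes of the list was in the table used here.

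Among lung lineage genes, the airway mucins rose and LAMP3 fell. Of 22 tested, 10 were higher, 2 lower (LAMP3 and MUC1) and 10 not called, with 11 higher and 4 lower adjusted over the list alone. The median log2 fold change was 0.40 and camera placed the list up (adjusted p = 0.0128; adjusted p = 0.273 with an estimated correlation), while the mean, pulled by LAMP3, was -0.29. The mucins MUC5AC and MUC5B rose from 27.6 ± 2.61 to 87.7 ± 12.4 CPM and from 27.2 ± 0.473 to 83.9 ± 6.24 CPM, alongside SPDEF. LAMP3, a lysosomal protein of type II cells and dendritic cells, fell from 57.0 ± 11.3 to 0.257 ± 0.0760 CPM (log2 fold change -7.79, adjusted p = 9.27e-12).

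Markers of other cell types were at low levels for the most part. Of 5 tested leukocyte markers CD68 and ITGAM were lower, CD14 was higher and CSF1R (0.310 ± 0.334 to 0.0912 ± 0.0976 CPM) was among the 2 not called, with the same 3 calls adjusted over the list alone (median log2 fold change -1.75, camera adjusted p = 0.0655). CD68, a lysosomal protein, fell from 162 ± 4.84 to 23.6 ± 0.0373 CPM, ITGAM from 5.36 ± 1.09 to 0.821 ± 0.00141 CPM, and CD14 rose from 1.31 ± 0.0772 to 2.80 ± 0.403 CPM. The pan-leukocyte gene PTPRC had 6 and 0 counts in the controls and 9 and 0 with overexpression. Of 9 fibroblast markers FAP was lower (1.30 ± 0.511 CPM to 3 counts, a ratio of 82.2 with a counting interval of 27.7 to 402) and 8 were not called, among them PDGFRB, C7 and COL1A1 (5.10 ± 1.64 to 6.56 ± 0.342 CPM). FAP was also the fibroblast call adjusted over the list alone; the list median was 0.035, the mean -1.68 and camera placed it down (adjusted p = 0.610). Of 5 endothelial markers CDH5 was higher (0.866 ± 0.499 to 2.90 ± 0.300 CPM) and 4 were not called, ESAM, TEK and PECAM1 among them, with CDH5 called adjusted over the list alone too (median -0.016, or 0.051 with library totals, mean 0.44, camera up, adjusted p = 0.619). Of 9 markers of kidney and cervix lines KRT17 and KRT14 were lower, at least 18.1-fold and 11.9-fold against 0 counts, and 7 were not called, PAX2 and TP63 among them; adjusted over the list alone PAX2 was lower as well (median -0.0027, or 0.064 with library totals, camera down, adjusted p = 0.411). Leaving out 1 library ended the calls of CD14 (adjusted p of 0.0997 without control library 1, 0.0676 without control library 2, 0.213 without CBX7 library 1 and 0.0544 without CBX7 library 2) and KRT14 (0.118 without control library 2). It brought the leukocyte list past the threshold without CBX7 library 1 (0.0121) or 2 (0.0181), and so did fry (0.00721), a mean count of 50 or more (0.0391), library totals (0.0425) and the replicate block (0.0462), but it did not pass with an estimated correlation (0.334). PDGFRB and C7 were called lower with limma-voom (0.0462 and 0.0328) and PAX2 at a mean count of 50 or more (0.0208). With 1 library left out, the log2 fold change of CDH5 ran from 1.26 to 2.50, that of FAP from -9.75 to -5.22 and that of KRT14 from -8.51 to -7.39.

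**Figure D3:**
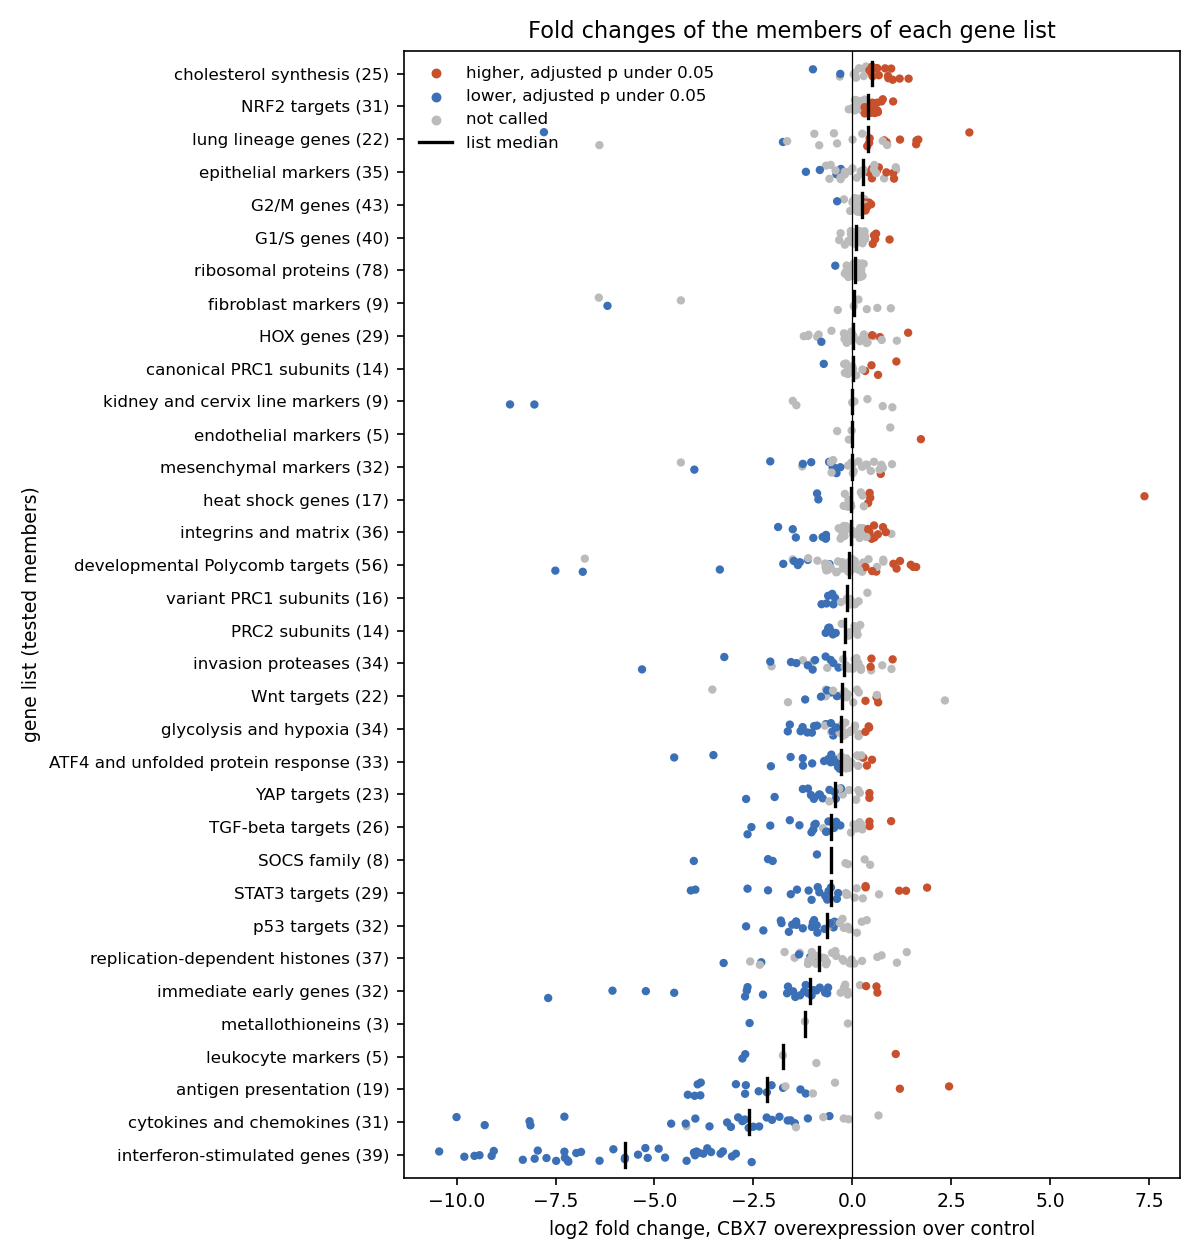
Log2 fold change of CBX7 overexpression over control (horizontal axis) for each tested member of the 34 tested gene lists (vertical axis, tested members in brackets), with called genes in red (higher) and blue (lower), the rest in grey, and a bar at each list median. Interferon-stimulated genes lie lowest, with a median of -5.75, and cholesterol synthesis genes highest, with a median of 0.50.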

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

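Most alternatives were chosen before the data were examined; library totals for the lists were chosen after seeing the data. CBX7 stayed higher (log2 fold change 1.04 to 1.20) and SOCS3 lower (-2.36 to -1.92), both called, under all 12 alternatives run on them. Counts of list members moved with library totals: G2/M genes higher from 10 to 22, G1/S genes higher from 6 to 10 and ribosomal proteins higher from 0 to 5. Counts of calls over all tested genes stayed within 1.5 times of those reported except in these cases. An adjusted p under 0.01 left 877 genes higher, 1520 lower and 227 higher by 2-fold, because fewer genes pass a stricter threshold. Leaving out 1 library gave 1021 (without CBX7 library 1) to 1790 (without control library 2) genes higher, and 1121 without CBX7 library 2; fewer samples were then compared. DESeq2 called 1984 higher and 2488 lower, limma-voom 1845 and 2467, and 4104 and 4102 of the 4208 calls kept their direction and call. In the simulated counts, which had fewer and smaller changes than these data, 7.47% of DESeq2 calls were false. With an estimated correlation 0 of the 20 gene lists passed camera, while 18 of the 20 kept their direction and call with fry. Fry asks whether list members change at all, and camera whether they change more than other genes. A pass with fry is therefore no check on the camera result. Camera with an estimated correlation had little power here: the interferon list, with all 39 members lower, had an unadjusted p of 0.0434 with it. The ATF4 and unfolded protein response list had an estimated correlation of 0.00107, below the preset 0.01. Its unadjusted camera p still went from 9.25e-06 to 0.0376. The invasion protease, G2/M, glycolysis and hypoxia, and lung lineage lists also had estimates below 0.01. Other lists that passed camera had higher ones, among them ribosomal proteins (0.844), metallothioneins (0.588), interferon-stimulated genes (0.440) and cytokines (0.143). For lists with such estimates the camera p at the preset correlation may be far too small, so low power is not the only difference.

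Reversed directions were confined, among the genes and lists reported, to results that were not called. When libraries were left out, the log2 fold change ranged from -3.72 to 0.316 for CSF1R, from -0.0667 to 6.52 for TEK, and from -6.83 to 0.911 for PECAM1 (0.0914 without control library 2). The integrins and matrix list turned up with library totals (adjusted p = 0.994), and its adjusted p lay between 0.591 and 0.974 over left-out libraries (0.779 where it turned). Heat shock genes turned down at a mean count of 50 or more (0.969) and with fry (0.861), and left-out libraries gave 0.597 to 0.922. Left-out libraries gave 0.519 to 0.958 for fibroblast markers, and a mean count of 50 or more turned the kidney and cervix markers up (0.934). The cause was not tested for these. Epithelial, mesenchymal and leukocyte markers passed with fry (0.00721, 0.0253 and 0.00721) but not with an estimated correlation (0.289, 0.405 and 0.334), and ribosomal proteins did not (0.647), nor at a mean count of 50 or more (0.0726). With the replicate block, 2100 genes were higher and 2503 lower, and 22 lists passed, the variant PRC1 and leukocyte lists being gained; KCNJ16, SLC1A7 and ADH6 lost their call (adjusted p of 0.0584, 0.0882 and 0.0551). The titles give same-numbered libraries nothing in common but the number, and their deviations from the group means correlated at 0.0281. That value does not exclude a shared batch, because genes with few counts weigh in it as much as the others. Of the 3 ways to split 4 libraries into pairs, the real one called 4208 genes and the others at most 2, and 3 splits are too few for a share under 0.05. The other splits put a control and a CBX7 library in each group, so the difference between lines counts there as spread within groups. Their few calls therefore do not measure how many of the 4208 are false. At this depth, 3 counts per library limit what can be seen to 0.0320 to 0.0440 CPM.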

Other observations

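Of 34 tested glycolysis and hypoxia genes, 14 were lower, 3 higher (CA12, PFKFB3 and SLC16A3) and 17 not called, with 20 lower and 3 higher adjusted over the list alone (median log2 fold change -0.28, camera adjusted p = 0.000105; adjusted p = 0.211 with an estimated correlation). Besides ANGPTL4, the histone demethylase KDM3A, adrenomedullin (ADM) and the collagen hydroxylase P4HA1 fell 2.47-fold, 1.95-fold and 1.86-fold. Integrins and matrix genes had 8 of 36 members higher, 8 lower and 20 not called, with 9 higher and 10 lower adjusted over the list alone (median -0.043, or 0.022 with library totals, camera adjusted p = 0.950). The collagen receptor subunit ITGA2 fell 2.84-fold, CCN1 fell 1.68-fold, and THBS1 rose 1.80-fold. Wnt targets had 5 of 22 lower, 3 higher and 14 not called, with the same counts of 5 and 3 adjusted over the list alone (median -0.26, camera adjusted p = 0.179). The Wnt antagonists SFRP1 and DKK3 fell 2.28-fold and 1.73-fold, MYC fell 1.55-fold and the antagonist DKK1 rose 1.53-fold.

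Heat shock genes had 4 of 17 higher, 2 lower and 11 not called, with 6 higher and 2 lower adjusted over the list alone. Their median was -0.038, or 0.028 with library totals, and the mean of 0.40 was pulled up by CRYAB, which had 0 counts in both controls and 19 and 26 with CBX7 overexpression (camera up, adjusted p = 0.789). The co-chaperones DNAJA1 and DNAJB4 fell 1.81-fold and 1.85-fold, while HSPA1A and DNAJB1 rose 1.37-fold and 1.36-fold. HSPA1A shares nearly all its sequence with HSPA1B, so the split between them is uncertain. By chromosome, the median log2 fold change of 12093 genes with a matched chromosome and a mean of 2 CPM or more ran from -0.082 on chromosome 21 to 0.11 on chromosome 19.

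The tests of explanations below were chosen after the result was seen. The control line had a strong interferon programme, and the CBX7 line nearly none. Scaling does not account for it, since the median of the 39 interferon-stimulated genes was -5.68 or lower under TMM, DESeq2 size factors and library totals. Leukocytes in the control cultures are argued against as the whole cause, as PTPRC, TYROBP, FCER1G and LYZ had control means of at most 0.0348 CPM, although CD68 (162 to 23.6 CPM) and ITGAM (5.36 to 0.821 CPM) of the same list fell with the interferon genes. Interferon production in the control cells is a candidate source: IFNB1, IFNL1, IFNL2 and IFNL3 summed to 109.8 CPM in the controls and 0.177 CPM with CBX7 overexpression. Whether repression by CBX7 itself removed the programme or the control line alone gained it cannot be told apart, because the series has 0 libraries of untransduced cells.

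SOCS3 was lower in both CBX7 libraries, as were other genes that cytokines induce. Lower cytokine and interferon signalling may account for part of the fall. SOCS1, also cytokine-induced, fell further than SOCS3 (log2 fold change -4.00 against -2.13). A fall of SOCS1 would also be seen if CBX7 repressed both genes directly, so it does not favour either account. Whether the loss of SOCS3 released STAT3 signalling cannot be told apart from lower signalling, because members of the list went both ways and some are receptors and kinases of the pathway or are induced by interferon. The 27 STAT3 targets left without SOCS3 and without members of the interferon, cytokine and antigen lists had a median log2 fold change of -0.39, with 15 lower and 5 higher (camera adjusted p = 0.0013, and 0.383 with an estimated correlation). Besides SOCS3, only ICAM1 was taken out of the tested members, and IRF1 (log2 fold change -4.08), JAK2 and STAT3 stayed in. This subset therefore does not separate STAT3 signalling from the interferon response. Direct repression of SOCS3 by CBX7 was not tested, as chromatin data were not analysed here.

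In the CBX7 libraries 40 genes were at 0 in both while both controls had 20 counts or more (95% Poisson interval 28.6 to 54.5). Zeros that count estimation may have left are common here: between 71 and 183 genes per library were at 0 with 20 or more counts in their replicate. What left each of these zeros was not tested. Of 14 genes at 0 with 200 or more in their replicate, 10 were read-through loci such as TMX2-CTNND1 (1641, 0, 1264 and 1396 counts). Zeros left by count estimation are argued against as the whole cause of the 40, since pairs of libraries that cross the groups shared at most 11. For the 13 genes at 0 in both controls (6.92 to 22.2) estimation zeros could account for the number, and the explanations cannot be told apart because the interval includes 11.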
